A study of Drosophila melanogaster with 3 samples.

How the data were processed

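The binding of Fs(1)h, a bromodomain protein of the BET family in Drosophila melanogaster, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in Kc167 cells, a cell line derived from late female embryos. There were 3 libraries. One was precipitated with an antibody to the long isoform alone (L), one with an antibody that binds both the long and the short isoform (LS), and one was sonicated input DNA. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 min, chromatin was sheared to 200 to 1000 bp, and library fragments of 200 to 300 bp were cut from a gel. Each group held 1 library, so there was no replicate error, and no test below compares conditions: every p-value treats regions of these libraries as the units.

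Per the submitters' processing notes, reads were aligned with Bowtie 0.12.5. The peak caller, its threshold, the use of the input and the genome build were not given in the sources used here. The names of the heterochromatin scaffolds (2LHet and the like) belong to release 5 of the fly genome, and positions are printed as deposited, converted to a first base of 1. The authors deposited, for each antibody, a list of regions with a sequence name, a start and an end, and no score, height, p-value or read count. The depth behind each region is therefore unknown. No processed file of the input was used here.

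The structure of the lists was tested before anything else. Every region wider than 1 bp had an identical start and end in both lists, and every region found in a single list was 1 bp wide. The authors' processing had thus already split the regions into shared and unshared, by a rule that was not given in the sources used here. The width of an unshared region and the amount of overlap were not measured values in these files. The 3 classes used throughout were the regions in both lists, the positions in the LS list alone and the positions in the L list alone.

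The analysis plan was fixed before the data were examined. It included tests of peak scores, score-filtered lists, distance to transcription start sites, genomic features, divergent promoters, DNA motifs and gene groups. None of these was run, because the lists hold no scores and no genome or annotation of their build was used here. A gene table of release 6 was left unused, since positions were not converted between builds. Regions were named by the planned rule, the 8 highest-scoring regions of each class with width in place of a missing score. The rule selects the 8 widest shared regions and no others, because all unshared positions are 1 bp wide.

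A region counted as shared when it overlapped a region of the other list by at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only, and a share of 0 carries the limit set by 3 counts, with the exact upper limit beside it. Odds ratios carry Woolf 95% intervals, with Fisher's exact test for the p-value. Where any count was 0, a small constant was added to each count for the odds ratio and its interval. Overlap was set against 1000 random placements of the L regions on the same sequences, from the first base to the largest end in either list. The share of LS regions with an L region was compared between each of the 11 sequences and the rest with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment. The distance between midpoints and the number of LS midpoints within 10 kb were compared between classes with two-sided permutation tests (100000 permutations, 10000 for alternatives). These spacing values are printed without their p-values, because widths were kept for shared regions and removed for the others. The following comparisons were chosen after the data were seen. They were Fisher's exact tests of 1 Mb windows with at least 10 LS regions against the rest of their sequence, of the centromere-proximal ends of the arms and of the heterochromatin scaffolds with chromosome 4. They also included tests of L-alone positions by sequence, of region width by sequence, of the distance to shared regions, and of the class of neighbouring regions. Fisher's exact test treats regions as independent, although neighbours shared their class more often than chance. Whole 1 Mb windows were therefore also permuted among sequences, for each sequence alone and not for the pooled group.

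Other overlap rules were reciprocal overlap of 50%, midpoints within 250 bp and edges within 500 bp. Further alternatives were the main arms alone, regions with gaps of up to 500 bp chained into blocks, edge-to-edge distances, a window grid shifted by 500 kb and classes permuted within 1 Mb windows, with and without chaining. The statistics were tested on simulated classes placed on the deposited LS regions. Each region's class was drawn independently in these runs, so they do not cover the likeness of neighbours in the deposited lists. With no difference simulated, 2 of 40 runs called any sequence and 0 of 40 called any window. A rise of 10 percentage points on the X was called in 40 of 40 runs. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.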

Results

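The binding sites of the long isoform of Fs(1)h were compared with those recovered by an antibody to both isoforms. The aim was to separate sites with a call for the long isoform from sites without one. A site without a call cannot be told from one below the authors' threshold. The L list held 4867 regions and the LS list 8423 regions, which made 8882 distinct regions. Of these, 4408 were in both lists, 4015 were in the LS list alone and 459 were in the L list alone. They lay on 5 long chromosome arms (2L, 2R, 3L, 3R and X), on the small, largely heterochromatic chromosome 4 and on 5 heterochromatin scaffolds. Each antibody was represented by 1 library.

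Nearly every site of the long isoform was also a site of the antibody to both isoforms, whereas the reverse held for only part of the LS list. Of the L regions, 90.6% (95% interval 89.7 to 91.4) were in the LS list. Of the LS regions, 52.3% (95% interval 51.3 to 53.4) were in the L list, which left 47.7% without a call for the long isoform. When the L regions were placed at random on the same sequences, on average 15.9% of them overlapped an LS region, and 17.6% was the highest of 1000 placements (permutation p = 0.001, the smallest these placements can give). The corresponding random share of LS regions was 10.5%, with 11.6% the highest (permutation p = 0.001). The lists had been divided into shared and unshared regions before deposit, so this comparison describes the authors' division. Unshared regions were listed as single bases, which a placed region seldom meets. The random shares are therefore too low a baseline for regions of full width. With edges within 500 bp accepted as overlap, 57.1% of the LS regions had an L region. Of the LS-alone positions, 397 lay within 500 bp of a shared region, whereas 1 L-alone position lay within 500 bp of an LS-alone one. The rise therefore came almost wholly from L regions that already matched an LS region of their own.

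The 4408 shared regions were 349 to 30200 bp wide, with a median of 1477 bp (quartiles 1017 and 2257 bp). They covered 8.52 Mb, which was 6.65% of the sequence up to the last listed base of each arm and scaffold. Of the 26 shared regions that were at least 10 kb wide, 10 lay on 3R, 6 on 3L, 5 on the X, 3 on 2R and 2 on 2L. The widest was a 30.2 kb region on 3L from 3427893 to 3458092, followed by a 26.9 kb region on 3L from 8667986 to 8694933. On the X, a region of 20.6 kb ran from 3325451 to 3346074 and another of 15.0 kb from 2186142 to 2201174. On 3R, wide regions ran from 19837617 to 19858234 (20.6 kb), from 25102206 to 25118656 (16.5 kb) and from 17404554 to 17418555 (14.0 kb). The eighth in rank was a region of 13.5 kb on 3L from 20385589 to 20399038. After regions with gaps of up to 500 bp were chained, the widest block ran on 3L from 8667986 to 8703544 (35.6 kb) and the third on the X from 5599925 to 5621194 (21.3 kb, 3 shared regions). Shared regions on the X had a median width of 1531 bp (n = 780), against 1467 bp on the autosomal long arms (n = 3605), and this difference of 63.5 bp did not pass the test (permutation test, two-sided, p = 0.138). The genes at these positions were not analysed here.

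The proportion of LS regions with a call for the long isoform differed between chromosomes. On 2L it was 46.5% (648 of 1394 regions), lower than on all other sequences together (53.5%; Fisher's exact test, adjusted p = 2.14e-05). On 3R it was 55.8% (1096 of 1963; exact adjusted p = 0.00224) and on 2R 55.6% (935 of 1681; exact adjusted p = 0.00491), both above the remaining sequences. The shares on 3L (52.6%, 926 of 1762) and on the X (51.6%, 780 of 1512) did not pass the test against the remaining sequences (exact adjusted p = 0.851 and 0.585). When whole 1 Mb windows were permuted among the sequences, 2L remained past the threshold (permutation adjusted p = 0.00935), whereas 2R and 3R did not (permutation adjusted p = 0.101 and 0.0511).

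Sites on heterochromatic sequence were mostly sites without a call for the long isoform. On chromosome 4 the long isoform was called at 12 of 44 LS regions (27.3%, 95% interval 15.0 to 42.8; exact adjusted p = 0.00299). On the scaffold 3LHet it was called at 8 of 33 (24.2%; exact adjusted p = 0.00299) and on 2RHet at 2 of 17 (11.8%; exact adjusted p = 0.00299). None of the 6 LS regions on 2LHet had an L region, which allows a share of up to 50% by 3 counts (exact upper 95% limit 45.9%; exact test, adjusted p = 0.0184), and none of the 5 on XHet, which allows up to 60.0% by 3 counts (exact upper 95% limit 52.2%; exact test, adjusted p = 0.0338). On 3RHet the long isoform was called at 1 of 6 LS regions, which did not pass the exact test (adjusted p = 0.134). With whole 1 Mb windows permuted, the call on XHet also ended (permutation adjusted p = 0.0522). It ended too after regions with gaps of up to 500 bp were chained (exact adjusted p = 0.0858). The odds ratio of XHet was then 0.0908, against 0.0827 before chaining, so the effect stayed about as large. The 5 scaffolds and chromosome 4 together had 23 of 111 LS regions with an L region (20.7%), against 4385 of 8312 on the long arms (52.8%). The odds ratio was 0.234 (95% interval 0.148 to 0.371; Fisher's exact test, two-sided, p = 8.38e-12). This pooled group was chosen after the data were seen, and whole windows were not permuted for it. Its interval and p-value take neighbouring regions as independent and so overstate the certainty.

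**Figure D1:**
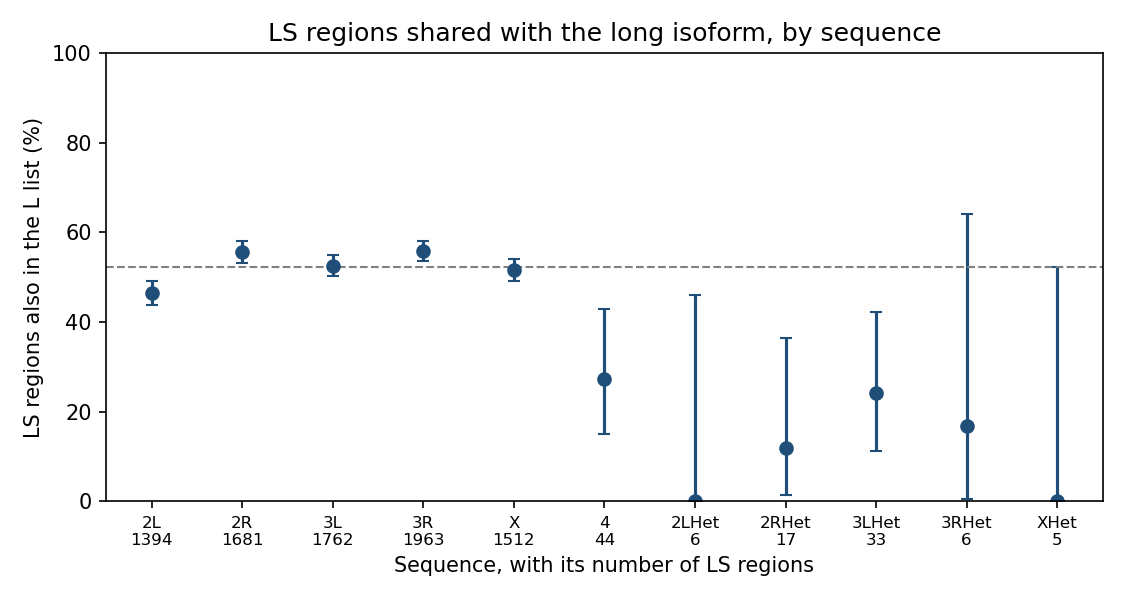
Percentage of LS regions that were also in the L list (vertical axis) on each arm and scaffold (horizontal axis, with the number of LS regions). Points are the shares, bars are exact 95% intervals and the dashed line is the share over all sequences (52.3%). The long arms lie between 46.5% and 55.8%, and chromosome 4 and the heterochromatin scaffolds lie at 27.3% or below.

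On long arms, the share of LS regions with an L region was lowest near the centromere-proximal ends of 2R and 3L and inside 2L. In 121 windows of 1 Mb with at least 10 LS regions, 118 of them on the long arms, 2 on 3LHet and 1 on chromosome 4, the median share was 53.1% and the range 9.09% to 75%, and 7 windows passed Fisher's exact test against the rest of their sequence. Of these, 5 were lower. On 2R the first 1 Mb had 9 of 43 LS regions with an L region (20.9%; exact adjusted p = 0.000392) and the next 1 Mb had 19 of 56 (33.9%; exact adjusted p = 0.0195). On 3L the window from 23 to 24 Mb had 2 of 22 (9.09%; exact adjusted p = 0.00105). On 2L the window from 4 to 5 Mb had 7 of 43 (16.3%; exact adjusted p = 0.00105) and that from 10 to 11 Mb had 15 of 70 (21.4%; exact adjusted p = 0.000714). The remaining calls were higher, on 2L from 6 to 7 Mb with 52 of 80 (65.0%; exact adjusted p = 0.0179) and on 3L from 5 to 6 Mb with 36 of 48 (75%; exact adjusted p = 0.0313). After regions with gaps of up to 500 bp were chained, both higher windows and the second window of 2R no longer passed (exact adjusted p = 0.0803, 0.147 and 0.0767). Their odds ratios were then 2.13, 2.33 and 0.420, against 2.24, 2.78 and 0.397 before chaining, with fewer regions in each, so the lost calls do not show that abutting pieces made these windows. With the grid shifted by 500 kb, 5 windows passed. The lower ones lay on 2L from 3.5 to 4.5 Mb (16%) and from 9.5 to 10.5 Mb (21.25%), on 2R from 0.5 to 1.5 Mb (8.16%) and on 3L from 23.5 to 24.5 Mb (0 of 13, which allows up to 23.1% by 3 counts, or 24.7% as the exact upper 95% limit). The higher one lay on 2L from 21.5 to 22.5 Mb (72.5%; exact adjusted p = 0.0334). The shifted windows that overlapped the higher windows of 2L (6 to 7 Mb) and 3L (5 to 6 Mb) did not pass (exact adjusted p from 0.248 to 0.875). Their odds ratios were 1.65 and 1.19 on 2L, against 2.24 on the first grid. On 3L they were 2.12 and 1.39, against 2.78. Shifted windows over another part of the lower windows also did not pass. They lay on 2R up to 0.5 Mb (30%; exact adjusted p = 0.242) and from 1.5 to 2.5 Mb (57.6%; exact adjusted p = 0.996). On 3L this was the window from 22.5 to 23.5 Mb (56.8%; exact adjusted p = 0.996). On 2L these were the windows from 4.5 to 5.5 Mb (34.4%; exact adjusted p = 0.299) and from 10.5 to 11.5 Mb (46.6%).

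The share at the 5 centromere-proximal ends ranged from 0% to 68.2%, and the difference between arms was not tested. The ends of 2R and 3L overlap the lower windows above and were chosen after the data were seen. Their tests are therefore not separate support for those windows. In the last 1 Mb before the largest listed position, none of the 13 LS regions of 3L had an L region, which allows up to 23.1% by 3 counts (exact upper 95% limit 24.7%; Fisher's exact test, adjusted p = 0.000147). In the last 1 Mb of the X, 6 of 25 had one (24.0%, against 52.1% on the rest of the X; exact adjusted p = 0.0125). The shifted window of the X from 21.5 to 22.5 Mb had 6 of 21 (28.6%; exact adjusted p = 0.289). No window of the X passed on either grid. The end of 2L had 50% (21 of 42; exact adjusted p = 0.642). This share depended on the limit, since the shifted window from 22.5 to 23.5 Mb had 3 of 17 (17.6%; exact adjusted p = 0.242). The first 1 Mb of 3R had 68.2% (45 of 66; exact adjusted p = 0.0545). Neither end was past the threshold. With the limit set at 2 Mb, only 2R was past the threshold (28 of 99 regions, 28.3%; exact adjusted p = 8.54e-08). Neither 3L (41.2%; exact adjusted p = 0.195) nor the X (50%; exact adjusted p = 0.810) was. The low share of 2R was not even over these 2 Mb, since its shifted window from 1.5 to 2.5 Mb had 57.6%.

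**Figure D2:**
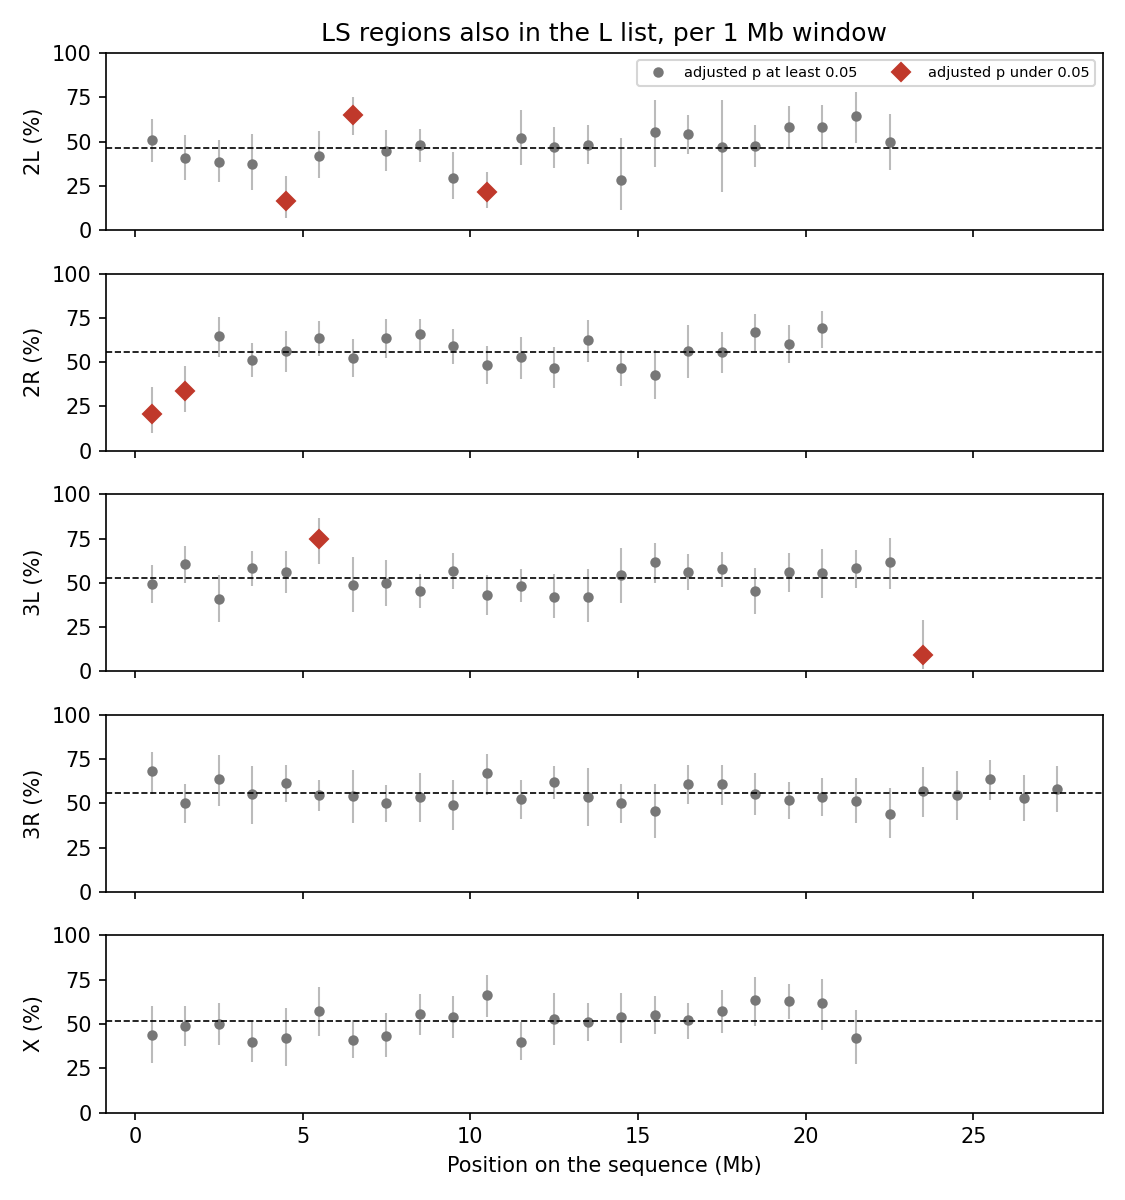
Percentage of LS regions that were also in the L list (vertical axes) in windows of 1 Mb along each long arm (horizontal axis, Mb). Bars are exact 95% intervals, dashed lines are the share of the whole arm, and red diamonds are the 7 windows with an adjusted p under 0.05. The first 2 windows of 2R and the window of 3L from 23 to 24 Mb lie at 20.9%, 33.9% and 9.09%.

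The spacing of sites with and without a call for the long isoform could not be compared in these lists. Shared regions kept their width whereas LS-alone sites were single bases, and this alone can set the order of the classes. The median distance to the nearest LS midpoint was 2541 bp for shared regions and 1907 bp for LS-alone positions, and the median distance between edges was 774 bp and 1414 bp. Within 10 kb of its midpoint, a shared region had 2.96 ± 1.96 other LS regions (SD over 4408 regions) and an LS-alone position 3.12 ± 2.04 (SD over 4015), a count that the width of shared regions also enters. Shared regions often abutted, since 600 of the 2360 pairs of neighbouring shared regions (25.4%) were under 200 bp apart and the closest pair was 2 bp apart.

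**Figure D3:**
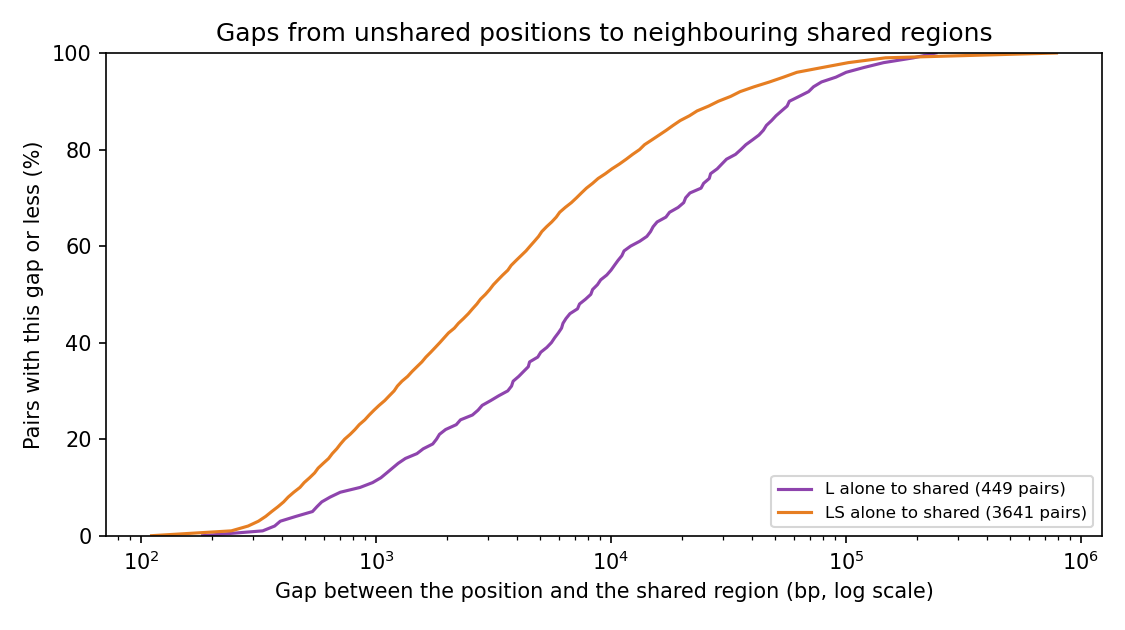
Cumulative percentage of neighbouring pairs (vertical axis) by the gap between them (horizontal axis, bp, log scale), for L-alone and LS-alone positions next to a shared region. Both kinds of position are single bases. The median gap is 8211 bp for L-alone and 2924 bp for LS-alone positions.

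Neighbouring LS regions were of the same class more often than under permutation, but abutting shared regions can raise this share. Of 8412 neighbouring pairs, 54.7% were both with or both without an L region, against 50.5% when classes were permuted within each sequence (permutation test, one-sided, p = 1e-05, the smallest these permutations can give). The difference was 4.15 percentage points. It was 2.40 points after regions with gaps of up to 500 bp were chained, 3.22 points with classes permuted within 1 Mb windows and 1.37 points with both (permutation p = 0.0082). With edges within 500 bp accepted as overlap it was 8.22 points, but that rule gives LS-alone positions the class of a close L region. Under 500 bp apart were 803 pairs of neighbouring shared regions, 404 pairs of an LS-alone position and a shared region and 19 LS-alone pairs. Chaining joined regions of any class, and so removed pairs of unlike class as well as abutting pieces. The chained values therefore cannot tell whether abutting pieces made the whole excess.

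The 459 positions listed for the long isoform alone lay farther from the shared regions than the LS-alone positions did. They made up 9.43% of the L list. Their share ran from 8.09% on 2L (57 of 705 L regions) to 10.7% on 3L (111 of 1037) among the long arms, and no sequence passed Fisher's exact test (smallest adjusted p = 0.725, with none at an unadjusted p under 0.05). The nearest shared region was at a median of 9.15 kb from an L-alone position (n = 459; quartiles 2.72 and 24.5 kb) and at 3.51 kb from an LS-alone position (n = 4004 on sequences with a shared region; quartiles 1.17 and 9.91 kb). The difference of 5.64 kb passed a two-sided permutation test (p = 1e-05, the smallest these permutations can give). The test treats the class labels as exchangeable, although each class was defined by absence from the other list. The LS list was also the larger (8423 regions, against 4867). An L region near a shared one could thus more easily meet an LS region and be classed as shared. How much this division adds to the difference was not tested. Within 5 kb of a shared region lay 35.3% of the L-alone and 59.1% of the LS-alone positions. Both classes were nearer to shared regions than random positions on the same sequences, whose medians were 14.5 kb for the L-alone number (central 95% of placements 11.6 to 17.3 kb) and 15.4 kb for the LS-alone number (14.5 to 16.5 kb).

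The densest stretches of each class were chosen after their values were seen, in windows of 100 kb. The most shared regions, 24, lay on 3R from 12000001 to 12100000, together with 8 LS-alone positions and no L-alone position. The most LS-alone positions, 16, lay on 2R from 6700001 to 6800000, with 6 shared regions. The most L-alone positions, 7, were reached on 3R from 19100001 to 19200000, with 4 shared regions, and on the X from 14800001 to 14900000, with 5 shared regions.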

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

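Of 131 recomputed values, 117 kept their direction and their side of the threshold, or stayed within the limits set for a value without a test. Requiring reciprocal overlap of 50% or midpoints within 250 bp changed none of 24 results under either rule. This follows from the identical coordinates of shared regions and says nothing about stability, although these results are counted in the 117. With edges within 500 bp accepted, 57.1% of LS regions had an L region, almost wholly because shared regions also counted as partners of close LS-alone positions. The spacing differences are shaped by the widths kept for shared regions alone. Between midpoints the difference was 634.5 bp, 207.5 bp with edges within 500 bp and 1807 bp after chaining, and it reversed to -640 bp between edges. The difference in LS regions within 10 kb was -0.155, -0.540 after chaining, and it reversed to 0.00732 with edges within 500 bp. The excess of same-class neighbours, 4.15 points, was 8.22 with edges within 500 bp, 2.40 after chaining, 3.22 with classes permuted within 1 Mb windows and 1.37 with both. Chaining and edge-to-edge distances were chosen after seeing the data, as were the window alternatives. Chaining joined regions of any class, and a block counted as shared if any member was. LS-alone regions thus fell from 4015 to 3598, and the chained shares are not those of rejoined shared pieces alone. Chaining gave 89.2% of L regions and 49.99% of LS regions with a partner, moved the called 1 Mb windows from 7 to 4, and left the odds ratio of 3L, never past the threshold, reversed at 0.982 (0.997 with the main arms alone). Of 11 sequences, 8 were called, 7 after chaining (XHet was lost), 4 of 6 with the main arms alone (fewer sequences tested) and 5 with whole 1 Mb windows permuted, where 2R, 3R and XHet were lost (odds ratios 1.18, 1.20 and 0.0827). Where no reason is given, the cause was not tested. Shifting the window grid by 500 kb called 5 windows, with none over either higher window of the first grid and a higher one on 2L from 21.5 to 22.5 Mb. Alternatives on scores, start sites, motifs and genes were not run, for lack of scores and of an annotation of the same build. No paired analysis was possible because each group held 1 library, and no library could be left out. Depth and region strength are unknown, so a site missing from the L list cannot be told from one below the authors' threshold.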

Other observations

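Every test in this part was chosen after the lists had been examined, and the predictions for the distance of L-alone to LS-alone positions and for the width of shared regions were written after the values were seen.

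The first pattern is the low share of LS regions with an L region on the heterochromatin scaffolds and chromosome 4. It was 23 of 111, against 4385 of 8312 on the long arms. A splitting of shared regions into abutting pieces would raise the shared count on the arms. After chaining of regions with gaps of up to 500 bp the odds ratio was 0.258 (95% interval 0.161 to 0.413, with regions taken as independent). This argues against splitting as the whole cause. Chaining also joined LS-alone positions to shared regions, so the part due to splitting was not measured. Weaker enrichment near the authors' threshold stays open, because width is the only proxy for strength in these lists and the 23 shared regions there differed from those on the long arms by -76 bp in the median (permutation test, two-sided, p = 0.741). A lower depth or efficiency of the L library, and reads shared between repeats, were not tested. Whether the short isoform is bound there with little of the long one was not tested, since that needs scores of the L signal at these sites or an antibody to the short isoform alone.

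The second pattern is that neighbouring LS regions share their class. After chaining, the excess of same-class neighbours was 2.40 percentage points (one-sided permutation p = 0.0002). This cannot decide whether abutting pieces account for all of it, because chaining joined regions of any class. Under 500 bp apart were 803 pairs of shared regions, but also 404 pairs of an LS-alone position and a shared region. Chaining thus removed pairs of unlike class too, which raises the same-class share. Broad differences in composition between stretches of 1 Mb account for part of it at most, since the excess fell from 4.15 to 3.22 percentage points over permutations within 1 Mb windows (permutation p = 0.0001, the smallest these permutations can give). With chaining and permutation within 1 Mb windows together it was 1.37 percentage points (permutation p = 0.0082). A grouping of sites of the same isoform composition at a scale below 1 Mb is a candidate explanation. Abutting pieces or regional differences in the strength of the L signal could give the same picture. That strength cannot be measured without scores.

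The third pattern is the group of 459 positions in the L list alone, although the second antibody also binds the long isoform. Shifted calls of one site in the 2 lists are an unlikely source of most of them, since 8.06% (95% interval 5.74 to 10.9) lay within 2 kb of an LS-alone position, against 11.0% for random placements (central 95% 8.06 to 14.2). Shifts shorter than the smallest spacing left in the lists may have been removed by the authors' division, whose rule was not given in the sources used here, and stay untested. Relative to the shared regions, an even scatter over all bases of the sequences was also excluded. The median distance to the nearest shared region, 9.15 kb, lay below the central 95% of 1000 random placements (11.6 to 17.3 kb). These placements used every base alike, so a scatter over only the stretches where regions can be called was not tested. Relative to the LS-alone positions an even scatter was not excluded. The median distance to them, 15.0 kb, lay inside the random range (14.8 to 20.4 kb; permutation p = 0.0719). A mixture of weak true sites and scattered false calls was not tested, and no biological explanation was tested.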
